A study of Macrobrachium nipponense with 36 samples.

How the data were processed

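RNA sequencing of gills, hepatopancreas and muscle of the oriental river prawn, Macrobrachium nipponense, was re-analysed from the deposited tables. Prawns had been kept at 0, 7, 14 or 21 ppt salinity, with 0 ppt as the control, and each of the 3 tissues had 3 libraries per salinity, 36 in all. The labels call the exposure long term and mention 30 prawns; neither its duration nor the way prawns were divided over libraries is given in the sources used here. Whether replicates were separate animals, pools or repeated libraries is therefore unknown. If they were not independent, the p-values below measure only the spread between these samples, which may be technical.

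The authors deposited 1 table per tissue with FPKM values (fragments scaled by transcript length and library size) per assembled transcript and library. Per the labels, libraries were made with a stranded mRNA kit, and Trimmomatic 0.39, HISAT2 and Bowtie2 were used, without a stated role for each. The genome build, the assembler, the program that gave FPKM and any scaling between libraries are not given in the sources used here. Transcripts at 0 in all libraries of a tissue were absent from its table. The tables held 91542 transcripts of 38462 loci for gills, 90518 of 37554 for hepatopancreas and 88748 of 36065 for muscle. A protein name was given for 62497, 62307 and 61952 of them. Positions, exons and transcript lengths could not be given, because no annotation with these identifiers was used here.

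Read counts were not analysed here, since the tables hold FPKM alone, so the depth of each library is unknown and no counting interval can be given. Low FPKM values of loci with a single transcript, where equal read numbers give ratios that pile up at the inverse ratio of depths, put the depth of each library relative to the first control replicate of its tissue at 1 to 1.15 in gills, 1 to 1.12 in hepatopancreas and 1 to 1.23 in muscle.

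Each tissue was fitted on its own with limma 3.58.1 in R 4.3.3 (statmod 1.5.0) on log2(FPKM + 1). Transcripts with at least 1 FPKM in at least 3 of the 12 libraries of the tissue were tested, 51346 in gills, 34966 in hepatopancreas and 22860 in muscle. Group means were fitted with lmFit and eBayes (trend and robust), and 7, 14 and 21 ppt were each compared with 0 ppt, two-sided. P-values were adjusted by Benjamini-Hochberg over all transcripts tested, with a threshold of 0.05. Fold changes are differences of the mean log2(FPKM + 1), which shrinks changes of transcripts with low values. A linear slope per ppt was fitted in each tissue, and the 21 ppt responses of each pair of tissues were compared by combining the separate fits. Because all 3 exposed groups of a tissue were compared with the same 3 controls, their results share the chance values of those controls. Figures were drawn in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

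Gene lists, 25 in all, were defined by patterns in the protein names. They covered Na+/K+-ATPase and V-type H+-ATPase, other ion transporters and channels, carbonic anhydrase, amino acid and organic osmolyte metabolism, glycolysis and gluconeogenesis, citrate cycle, oxidative phosphorylation, fatty acid metabolism, antioxidant and detoxification enzymes, and heat shock proteins and chaperones. Further lists were innate immunity, hemocyte markers, apoptosis and lysosome, ribosomal proteins, translation factors, proteasome and ubiquitin, DNA replication and cell cycle, cuticle, chitin and moulting, cytoskeleton and junctions, and nervous system. Markers of other tissues and cells were the lists of muscle contractile proteins, digestive enzymes of the hepatopancreas, hemocyanin and respiratory proteins, vitellogenesis and gonad, and collagen and extracellular matrix. A transcript may be in several lists, and isoforms of 1 locus count as separate members. Lists were tested with camera of limma at a preset correlation of 0.01, adjusted over 225 tests (25 lists in 9 comparisons), and again with an estimated correlation. Members past the threshold were also counted with p-values adjusted over the list alone.

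Genes are named by a rule: per comparison, up to 5 transcripts per direction with the largest change among those past the threshold, with a mean of at least 5 FPKM, all 3 exposed libraries on the same side of all 3 controls and an informative protein name. The mean is taken over the 12 libraries of the tissue. Per list, up to 2 members per direction were added under the same conditions. Whatever their p, the most abundant transcript of each of 10 kinds was named in each tissue. These kinds were Na+/K+-ATPase alpha and beta, V-type proton ATPase subunit A, carbonic anhydrase, sodium/hydrogen exchanger, Na-K-Cl cotransporter, glutamate dehydrogenase, glutamine synthetase, arginine kinase and hemocyanin. The groups, tests, thresholds, lists and naming rule were chosen before the data were examined.

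The alternatives chosen then were a pseudocount of 0.1, no filter on low values, quantile normalization, the replicate number as a block, only the 6 libraries compared, a minimum absolute log2 change of 1, an F test over the 4 groups, an estimated correlation, and each library left out in turn. After the data were seen, these were added: FPKM summed per locus, leaving out the libraries with at least 5 FPKM of vitellogenin receptor, this receptor's level as a covariate, only the 6 libraries compared with the replicate block, locus sums with this block at 21 ppt, and a test of list differences between tissues. A further addition was a difference between tissues taken per salinity and replicate number.

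The labels do not say whether equal replicate numbers belong together. After centring by salinity, the correlations of all 3 same-numbered pairs of 0 and 21 ppt were over 0.1 in gills (0.116 to 0.193) and in muscle (0.107 to 0.242), and in none of the 7 other comparisons with 0 ppt. In these 2 comparisons the numbers were taken as pairs on that ground alone, and blocked values are given where a call changed. This was decided after the blocked counts had been seen.

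The procedure was tested on simulated data of the same size and spread, with 50 changed transcripts per size of change. Of transcripts changed by 3 on the log2 scale between 2 groups of 3, the test called 60% in gills, 76% in hepatopancreas and 66% in muscle, and of those changed by 2 it called 16%, 48% and 20%. It called 5 of 51106, 6 of 34726 and 3 of 22620 unchanged transcripts. Slopes that reach a change of 4 at 21 ppt were called for 82%, 84% and 80% of transcripts.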

Results

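RNA of gills, hepatopancreas and muscle of oriental river prawns kept at 0, 7, 14 or 21 ppt salinity was sequenced, with 3 libraries for each of the 12 combinations. The gills take up and excrete ions, the hepatopancreas is the main organ of digestion and storage, and muscle makes up most of the abdomen. Depth in reads is unknown. The FPKM values of a library summed to 644830 to 736670 in gills, 630010 to 808380 in hepatopancreas and 388390 to 507090 in muscle. The 10 most abundant transcripts held 7.00% to 11.6%, 8.96% to 12.4% and 14.4% to 22.7% of this sum. The median correlation of log2 values between libraries of the same salinity was 0.714 in gills, 0.8002 in hepatopancreas and 0.776 in muscle, beside 0.670, 0.785 and 0.780 between libraries of different salinities. Each salinity was compared with 0 ppt within a tissue, which asks what long-term exposure to that salinity does to the tissue's transcripts. The median log2 change of all transcripts tested at 7, 14 and 21 ppt was 0.11, 0.16 and 0.09 in gills, -0.02, -0.03 and 0.08 in hepatopancreas, and 0.10, 0.22 and 0.21 in muscle. Changes of gene lists are given relative to it, as the median of the members minus the median of all transcripts.

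Some libraries stood apart from others of their own salinity by transcripts typical of ovary. The vitellogenin receptor (MSTRG.26814.1), through which oocytes take up yolk protein, had 190 FPKM in the second gill library of 7 ppt. It had 113 and 103 FPKM in the second and the third of 14 ppt, and 101 and 65.6 FPKM in the second and the third of 21 ppt. In the other gill libraries, all 3 controls included, it had at most 0.673 FPKM. An ATP-dependent RNA helicase named VASA-like (MSTRG.20931.1), a marker of germ cells, had 154, 116, 129, 132 and 66.1 FPKM in these 5 libraries. It also had 6.19 FPKM in the first gill library of 7 ppt and 12.9 FPKM in the first of 14 ppt. In the remaining gill libraries it had at most 0.147 FPKM. Libraries without the receptor can thus still hold germline RNA. In hepatopancreas the vitellogenin receptor had 8.86 FPKM in the third control, 20.7 FPKM in the second library of 7 ppt and 13.1, 24.4 and 13.1 FPKM in the 3 libraries of 21 ppt, and at most 0.827 FPKM in the others. In muscle it did not exceed 0.915 FPKM. The libraries with at least 5 FPKM are called receptor-positive libraries below. The axis that held most variance among gill libraries (40.9%) separated them from the rest. Since all gill controls were without the receptor, values without these libraries are given beside each count for 7, 14 and 21 ppt in gills.

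**Figure D1:**
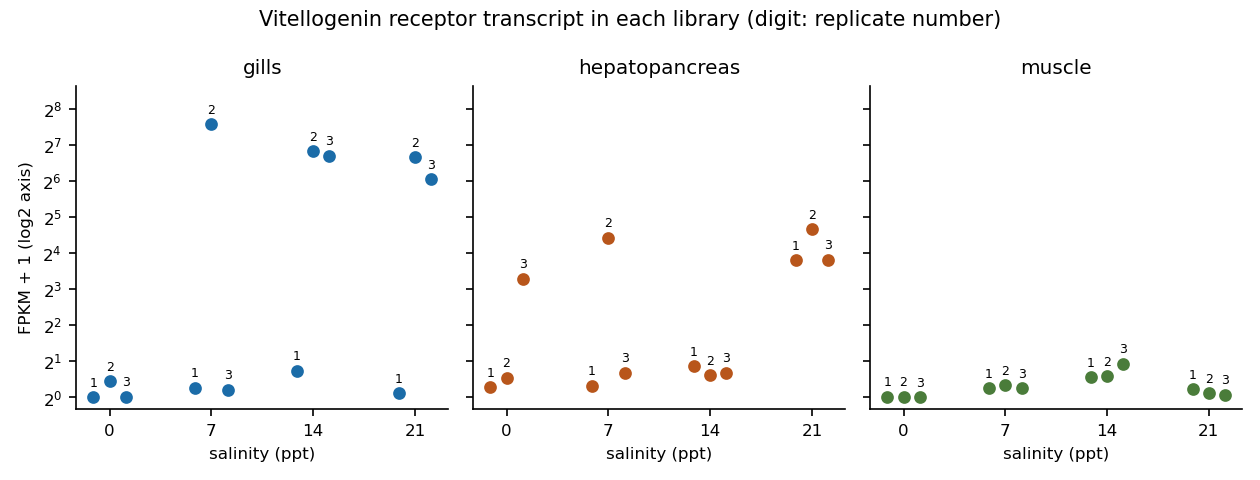
Level of the vitellogenin receptor transcript (FPKM + 1, log2 axis) in each of the 36 libraries by salinity (ppt) and tissue; each point is 1 library and its digit is the replicate number. In gills 5 exposed libraries lie between 65.6 and 190 FPKM and the 7 others at or below 0.673 FPKM.

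At 7 ppt a protease inhibitor transcript and an antimicrobial peptide transcript of the gills were among the 17 that fell. Turripeptide Ici9.2-like (MSTRG.6710.1), a name given to small Kazal-type protease inhibitors, went from 29.1 ± 11.9 FPKM (SD, n = 3) at 0 ppt to 0.361 ± 0.622 FPKM (n = 3), a log2 change of -4.48 (SE 0.52, adjusted p = 0.0256). Outside the naming rule, and chosen after their values were seen, were crustin 5 (MSTRG.22203.1), a cysteine-rich antimicrobial peptide, which fell from 17.9 ± 9.75 to 0.0824 ± 0.143 FPKM (log2 change -4.01, SE 0.43, adjusted p = 0.0182), and the four-domain proteases inhibitor (MSTRG.6725.1). The latter fell from 11.1 ± 2.42 FPKM by 3.57 on the log2 scale (adjusted p = 0.0216). The transcript that rose, MSTRG.7910.1, codes for an uncharacterized protein and went from 0.00181 to 11.2 ± 2.85 FPKM (log2 change 3.58, adjusted p = 0.0143), also chosen after the values were seen. Exposed and control libraries did not overlap for the turripeptide and crustin 5. The naming rule asks for this, and crustin 5 was chosen after its values were seen, so it is no further support.

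Of 51346 transcripts tested in gills at 7 ppt, 1 rose and 17 fell (limma, adjusted p under 0.05), and 2725 had an unadjusted p under 0.05. The falls included isoforms MSTRG.32005.22, MSTRG.32005.23, MSTRG.32005.24 and MSTRG.32005.34 of 1 locus, whose sum did not pass. MSTRG.32005.22 and MSTRG.32005.24 had identical values. The counts were 0 without control 1 or 3, 4 without control 2 or the first exposed library, and 3 without the second or the third exposed library. The turripeptide passed in none of these 6 fits (log2 change -4.83 to -4.20). Without the receptor-positive library 1 transcript passed, none of those passing with it, and with FPKM summed per locus 1 locus rose and 4 fell of 27456. A pseudocount of 0.1 gave 6 rises and 7 falls.

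Gene lists in gills at 7 ppt went down for the most part. Of 446 transcripts for cuticle, chitin and moulting 373 were lower and 73 higher (relative median log2 change -1.27, adjusted p = 1.3e-16). Of 40 for hemocyanin and respiratory proteins, the oxygen carriers of hemolymph, 36 were lower (-1.12, adjusted p = 9.5e-14). The 126 transcripts for DNA replication and cell cycle went up, with 111 higher (0.37, adjusted p = 9.3e-07), as did 674 for proteasome and ubiquitin, with 489 higher (0.12, adjusted p = 0.0107). Lower lists were muscle contractile proteins (435 of 666 lower, -0.35, adjusted p = 9.1e-06), hemocyte markers (105 of 183, -0.28, adjusted p = 2.3e-05) and innate immunity (407 of 668, -0.28, adjusted p = 0.000129). Lower too were digestive enzymes (150 of 250, -0.26, adjusted p = 0.00328), amino acid and organic osmolyte metabolism (106 of 185, -0.21, adjusted p = 0.0301) and collagen and extracellular matrix (140 of 242, -0.18, adjusted p = 0.0151). None of these 10 calls held with an estimated correlation, with adjusted p = 0.825 to 0.915. Without the receptor-positive library 6 lists were called, 5 of them among these 10 in the same direction, and hemocyte markers, digestive enzymes, osmolyte metabolism, collagen and proteasome were no longer called. With adjustment over the list alone, 10 of 183 hemocyte markers fell against 1 over all transcripts tested, and 6 of 668 innate immunity transcripts against 1. The hemocyte markers that fell were crustins and peroxinectin, a hemocyte adhesion protein (MSTRG.16958.2), with 36.3 ± 7.80 FPKM at 0 ppt and 12.4 ± 4.66 FPKM at 7 ppt. Crustin 7 (MSTRG.32507.2) was at 95.6 ± 36.9 FPKM at 0 ppt and practically at 0 in all 3 libraries of 7 ppt. In the list of other ion transporters, sodium bicarbonate transporter-like protein 11 (MSTRG.5079.1), a member of the bicarbonate transporter family, rose over the list alone (adjusted p = 0.00420) from 0.331 ± 0.260 to 8.07 ± 3.50 FPKM.

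At 14 ppt the same pair of transcripts was again among the gill transcripts that fell. Turripeptide Ici9.2-like (MSTRG.6710.1) was at 0.244 ± 0.275 FPKM (n = 3) against 29.1 ± 11.9 FPKM at 0 ppt (log2 change -4.54, SE 0.52, adjusted p = 0.0331). Crustin 5 (MSTRG.22203.1), chosen after its value was seen, was at 0.132 ± 0.163 FPKM (log2 change -3.94, SE 0.43, adjusted p = 0.0254). Chosen likewise, the unnamed transcript MSTRG.3165.1 fell from 218 ± 64.9 to 4.93 ± 0.817 FPKM (log2 change -5.17, adjusted p = 0.00267). Because the same 3 controls served each salinity, a high value in them moves all 3 comparisons.

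Of 51346 transcripts 0 rose and 6 fell (limma, adjusted p under 0.05), and 6953 had an unadjusted p under 0.05. The counts were 0 without control 1 or 3, 4 without control 2 or the first exposed library, and 8 without the third. The turripeptide passed in none of the fits without 1 of the 6 libraries (log2 change -4.86 to -4.26). Without the pair of receptor-positive libraries, which leaves a single library at 14 ppt assumed to vary like the other groups, 1 transcript passed, none of the 6, and 1 locus passed with FPKM summed per locus. A pseudocount of 0.1 gave 5 rises and 6 falls. Most calls were rises, 190 against 84 falls, when only the 6 libraries compared were fitted.

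The lists called at 14 ppt in gills were 16. DNA replication and cell cycle was higher (116 of 126 transcripts, relative median 0.84, adjusted p = 9.2e-13). Higher too were heat shock proteins and chaperones (199 of 268, 0.25, adjusted p = 0.00536) and proteasome and ubiquitin (510 of 674, 0.18, adjusted p = 0.00264). Muscle contractile proteins (487 of 666 lower, -0.72, adjusted p = 1.6e-15), cuticle (366 of 446, -1.24, adjusted p = 1.6e-14) and collagen (177 of 242, -0.39, adjusted p = 5.5e-08) were lower. So were hemocyte markers (108 of 183, -0.29, adjusted p = 2.9e-05), innate immunity (376 of 668, -0.28, adjusted p = 9.6e-05) and digestive enzymes (149 of 250, -0.37, adjusted p = 0.0036). The same call was made for Na+/K+-ATPase and V-type H+-ATPase, the pumps that drive ion uptake (28 of 36, -0.41, adjusted p = 0.00629). Amino acid and osmolyte metabolism (103 of 185, -0.26, adjusted p = 0.00804), other ion transporters (106 of 181, -0.28, adjusted p = 0.00949) and carbonic anhydrase (23 of 47, -0.15, adjusted p = 0.0210) were called lower. Oxidative phosphorylation (102 of 201, -0.17, adjusted p = 0.0224), hemocyanin (26 of 40, -0.33, adjusted p = 0.034) and citrate cycle (47 of 78, -0.20, adjusted p = 0.0365) were also called lower. The set of 386 transcripts typical of gill was lower here too. Its median was 65.6%, 53.3% and 40.6% of control in the 3 libraries of 14 ppt. Being chosen by control levels may account for part of this fall. Lower lists are not told apart from it. None of the 16 held with an estimated correlation, with adjusted p = 0.719 to 0.915. Fewer lists were called without the receptor-positive libraries, a fit that leaves the first library of 14 ppt alone. That library had the VASA-like transcript at 12.9 FPKM and a testis-specific protein kinase (MSTRG.37018.1) at 337 FPKM. The fit therefore does not remove germline RNA, and calls kept in it are no further support. Over the list alone 16 hemocyte markers fell and 1 rose (1 fell over all transcripts), and 10 innate immunity transcripts fell (1 over all). The crustin-like protein MSTRG.31639.1 was at 437 ± 224 FPKM at 0 ppt and 51.7 ± 14.5 FPKM at 14 ppt, and the crustin that rose, MSTRG.21350.1, at 0.455 ± 0.542 and 13.0 ± 6.85 FPKM. In the list of vitellogenesis and gonad, Nanos (MSTRG.20581.1), a germline RNA-binding protein, rose over the list alone from 0.0533 ± 0.0544 to 15.2 ± 13.6 FPKM. It had 30.9 FPKM in the first library of 14 ppt and 6.81 and 7.89 FPKM in the receptor-positive ones. A response of the gill is not told apart from germline RNA in these samples.

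At 21 ppt a transcript of the gill sodium pump was 1 of 20 that fell. Sodium-potassium ATPase beta (MSTRG.20654.1), the subunit that brings the pump to the membrane, fell from 192 ± 35.8 to 26.5 ± 9.09 FPKM (SD, n = 3; log2 change -2.85, SE 0.30, adjusted p = 0.0147). With the replicate number as a block it did not pass (adjusted p = 0.0758). It was at 58.7 ± 15.4 FPKM at 7 ppt and 44.6 ± 5.21 FPKM at 14 ppt. The other abundant transcript of the locus, beta-like MSTRG.20654.2, was at 118 ± 25.2 FPKM at 0 ppt and 170 ± 35.4 FPKM at 21 ppt and did not pass (log2 change 0.52, adjusted p = 0.665). The sum of the locus (MSTRG.20654), 310 ± 59.7 against 197 ± 44.4 FPKM, did not pass either (-0.66, adjusted p = 0.589). How reads were divided between these isoforms is not given. The catalytic alpha subunit (MSTRG.6597.3) was at 356 ± 54.6 FPKM at 0 ppt and 189 ± 33.9 FPKM at 21 ppt (log2 change -0.91, SE 0.28, adjusted p = 0.665), with all 3 exposed libraries below all 3 controls. The 386 transcripts typical of gill stood at a median of 77.0%, 47.0% and 56.9% of control in these exposed libraries. A change of the pump is not told apart from this general fall.

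Further gill transcripts named by the rule at 21 ppt were 4. The one named 50 kDa gamma-zein-like (MSTRG.20974.1), after a plant seed protein, fell from 95.9 ± 5.06 to 5.32 ± 1.08 FPKM (n = 3; log2 change -3.95, SE 0.41, adjusted p = 0.0147). Hybrid signal transduction histidine kinase L-like (MSTRG.20166.7) fell from 41.8 ± 11.6 to 5.13 ± 1.55 FPKM (log2 change -2.80, SE 0.38, adjusted p = 0.0462), and its locus fell too (-3.04, adjusted p = 0.0324). Turripeptide Ici9.2-like (MSTRG.6710.1) was at 1.01 ± 1.37 FPKM (log2 change -4.03, SE 0.52, adjusted p = 0.0447). Blastula protease 10-like (MSTRG.10624.7), of the astacin family of metalloproteases, rose from 0.0543 ± 0.0940 to 16.2 ± 5.05 FPKM (log2 change 3.99, SE 0.53, adjusted p = 0.0447). Another isoform, MSTRG.10624.16, fell from 11.2 ± 4.13 to 0.728 ± 0.260 FPKM (log2 change -2.77, adjusted p = 0.0462) and the sum of the locus stood at -0.04. Chosen after the values were seen, crustin 5 (MSTRG.22203.1) was at 0.806 ± 0.789 FPKM (log2 change -3.36, adjusted p = 0.0447). Likewise chosen, cationic amino acid transporter 4-like (MSTRG.20454.4) fell from 8.04 ± 2.76 to 0.248 ± 0.243 FPKM (log2 change -2.83, SE 0.34, adjusted p = 0.0319). The locus of a diuretic hormone receptor-like protein (MSTRG.36255), of a family that controls fluid secretion, fell from 11.2 ± 2.07 to 1.80 ± 0.564 FPKM (log2 change -2.13, SE 0.25, adjusted p = 0.0324), also chosen after its values were seen. With the replicate block none of these transcripts passed, with the same log2 changes. Adjusted p was 0.0626 for the gamma-zein-like transcript, 0.0621 for the histidine kinase-like one, 0.143 for the turripeptide, 0.153 and 0.0796 for the protease isoforms, 0.101 for crustin 5 and 0.0889 for the amino acid transporter. Of the loci, that of the histidine kinase passed with the block (adjusted p = 0.0198) and that of the diuretic hormone receptor did not (0.0926).

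Of 51346 transcripts 2 rose and 20 fell at 21 ppt in gills (limma, adjusted p under 0.05), and 3229 had an unadjusted p under 0.05. The count was 0 without control 3, 1 without control 2, 2 without control 1, and 4 without the second or the third exposed library. Without any 1 control, or without the second exposed library, neither ATPase beta (log2 change -2.997 to -2.73) nor the gamma-zein-like transcript (-3.99 to -3.82) passed, and the latter did not pass without the third either (-3.96). The turripeptide did not pass without any 1 control or without the first or the third exposed library (-4.36 to -3.63). The histidine kinase-like and blastula protease transcripts did not pass without any 1 of the 6 libraries (-3.01 to -2.59 and 3.77 to 4.16). It was 0 without the receptor-positive libraries, where the single library left is assumed to vary like the other groups and ATPase beta stood at -3.30 without passing, and 1 locus rose and 4 fell with FPKM summed per locus, or 0 and 2 with the replicate block as well. With the replicate block 0 transcripts rose and 3 fell, all among the 22, and 0 passed when only the 6 libraries compared were fitted with it. Without the block those 6 gave 5 rises and 5 falls, and a pseudocount of 0.1 gave 4 rises and 3 falls.

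A transcript with the symbol Trek2, the name of a potassium channel, also fell in gills at 21 ppt. It codes for a hypothetical protein (MSTRG.29405.2), was chosen after its values were seen and went from 12.9 ± 4.71 to 0.730 ± 0.573 FPKM (log2 change -2.99, adjusted p = 0.0462, 0.171 with the replicate block). The ion transport genes followed in all tissues, apart from the ATPase beta isoform above, did not pass over all transcripts. The Na-K-Cl cotransporter (MSTRG.36703.1) was at 102 ± 9.57 FPKM at 0 ppt and 72.2 ± 18.02 FPKM at 21 ppt (adjusted p = 0.665). V-type proton ATPase subunit A (MSTRG.30241.1) was at 190 ± 80.9 and 142 ± 61.1 FPKM (adjusted p = 0.787), and sodium/hydrogen exchanger 8-like (MSTRG.5804.2) at 5.88 ± 0.726 and 9.34 ± 3.04 FPKM. With adjustment over the 181 other ion transporters alone, 1 rose and 1 fell at 21 ppt, against 0 over all. The sodium-chloride cotransporter (MSTRG.7428.2) fell from 62.6 ± 2.41 to 14.4 ± 4.71 FPKM (log2 change -2.09, SE 0.32, list-alone adjusted p = 0.0104). Bicarbonate transporter-like protein 11 (MSTRG.5079.1) rose to 5.14 ± 1.204 FPKM (log2 change 2.21, list-alone adjusted p = 0.0126). A GPI-linked carbonic anhydrase (MSTRG.35708.1), the most abundant of its kind, was at 0.305 FPKM at 0 ppt and 55.7 ± 62.8 FPKM at 21 ppt; among the 12 gill libraries it exceeded 0.915 FPKM in the 5 receptor-positive ones alone. Among genes of nitrogen and energy metabolism, glutamate dehydrogenase (MSTRG.11499.4) was at 128 ± 47.3 and 74.2 ± 8.25 FPKM and glutamine synthetase (MSTRG.23145.1) at 178 ± 61.9 and 229 ± 54.8 FPKM. Arginine kinase 1 (MSTRG.38076.2) was at 1282 ± 173 and 1080 ± 351 FPKM and hemocyanin (MSTRG.15218.28) at 75.4 ± 48.7 and 22.5 ± 22.4 FPKM. None of these passed.

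**Figure D2:**
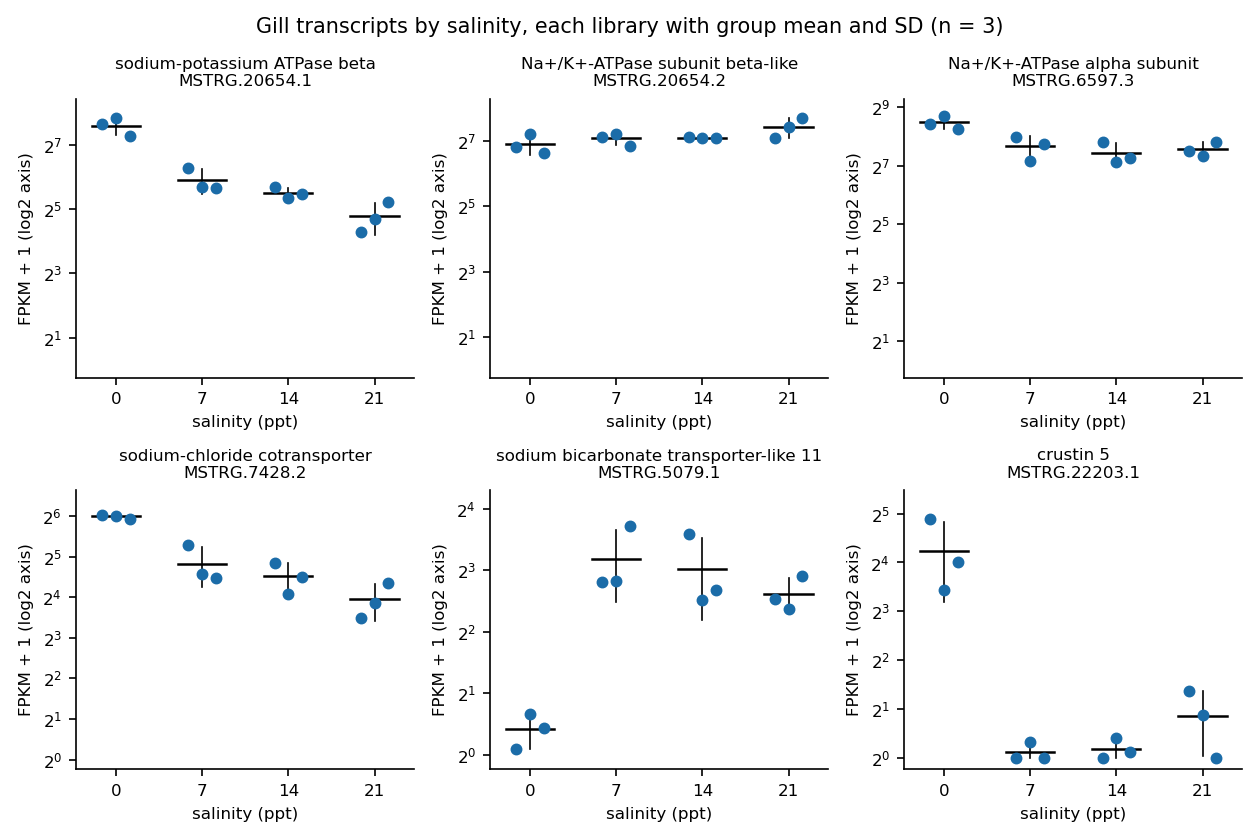
FPKM + 1 on a log2 axis against salinity (ppt) for 6 gill transcripts; points are libraries, the line is the mean of 3 and the bar their SD. Sodium-potassium ATPase beta goes from a mean of 192 FPKM at 0 ppt to 26.5 FPKM at 21 ppt, while the beta-like isoform goes from 118 to 170 FPKM.

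Of the lists in gills at 21 ppt, 2 were higher and 10 lower. DNA replication (111 of 126 transcripts higher, relative median 0.54, adjusted p = 2.3e-09) and heat shock proteins (185 of 268, 0.18, adjusted p = 0.0375) were the higher ones. Hemocyanin (36 of 40 lower, -0.87, adjusted p = 2.3e-09), contractile proteins (473 of 666, -0.46, adjusted p = 4.3e-08), the ATPase pumps (27 of 36, -0.42, adjusted p = 0.0125) and carbonic anhydrase (27 of 47, -0.53, adjusted p = 0.00328) were lower. Also lower were collagen (160 of 242, -0.24, adjusted p = 0.00252), hemocyte markers (93 of 183, -0.10, adjusted p = 0.00328) and digestive enzymes (138 of 250, -0.24, adjusted p = 0.00804). The same held for cuticle (253 of 446, -0.22, adjusted p = 0.0261), other ion transporters (100 of 181, -0.16, adjusted p = 0.0283) and amino acid and osmolyte metabolism (98 of 185, -0.13, adjusted p = 0.0443). None of the 12 held with an estimated correlation, with adjusted p = 0.825 to 0.915. Lower lists, the pumps among them, are not told apart from the fall of transcripts typical of gill given above. Without the receptor-positive libraries 4 of the 12 were called in the same direction, which were the ATPase pumps, hemocyanin, carbonic anhydrase and digestive enzymes. Over the list alone, 13 hemocyte markers fell and 2 rose (1 fell over all transcripts; 9 fell and 2 rose with the replicate block), 5 of 668 innate immunity transcripts fell (1 over all; 2 with the replicate block), and of osmolyte metabolism 2 fell and 1 rose (1 fell over all). The crustin-like protein MSTRG.31639.1 was at 20.4 ± 12.8 FPKM and crustin 1 (MSTRG.31638.1) at 13.8 ± 12.1 FPKM at 21 ppt, against 437 ± 224 and 118 ± 9.54 FPKM at 0 ppt. The neutral amino acid transporter B(0)AT2-like (MSTRG.31525.3) rose over the list alone, from 0.224 ± 0.387 to 2.90 ± 1.08 FPKM.

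A linear change with salinity was tested in each tissue. The gamma-zein-like transcript (MSTRG.20974.1) of the gills passed, with a slope of -0.18 on the log2 scale per ppt (limma, adjusted p = 0.0163). Its mean went from 95.9 FPKM at 0 ppt over 35.0 and 18.3 FPKM to 5.32 FPKM at 21 ppt. It was the single transcript of 51346 in gills, where 4420 had an unadjusted p under 0.05, and it did not pass without the receptor-positive libraries (slope -0.18, adjusted p = 0.208), where its change at 21 ppt was -3.72. Nor did it pass with the replicate block (adjusted p = 0.0558), without the filter on low values (0.0679) or with the receptor's level as a covariate (0.156). The count of slopes was 0 without any 1 control, the first library of 14 ppt or any 1 library of 21 ppt, and up to 5 without 1 of the others. No transcript passed among 34966 in hepatopancreas or 22860 in muscle (limma), with 3266 and 1378 at an unadjusted p under 0.05. An F test over the 4 groups passed 10 transcripts in gills, 5 in hepatopancreas and 29 in muscle.

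At 7 ppt an enzyme of betaine breakdown fell in hepatopancreas when adjusted over its list alone. Betaine-homocysteine S-methyltransferase 1 (MSTRG.30485.1), which passes a methyl group of the osmolyte betaine to homocysteine, was at 748 ± 317 FPKM (SD, n = 3) at 0 ppt and 79.7 ± 13.4 FPKM at 7 ppt. Its log2 change was -3.15. Over this list alone 4 of 200 members fell and 0 rose, against 0 over all transcripts. The others were dimethylglycine dehydrogenase (MSTRG.30486.1, log2 change -2.62), the next enzyme of the pathway, and a pair of glycine N-methyltransferase-like isoforms. The list as a whole was not called in hepatopancreas (adjusted p = 0.422 at 7 ppt, 0.906 at 14 ppt and 0.157 at 21 ppt), though at 21 ppt it was lower with FPKM summed per locus (adjusted p = 0.0103). The transcript that passed over all, MSTRG.35408.19, codes for an uncharacterized protein and rose from 0.0597 to 4.91 ± 1.43 FPKM (log2 change 2.45, adjusted p = 0.0363), chosen after its values were seen.

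Of 34966 transcripts 1 rose and 0 fell in hepatopancreas at 7 ppt (limma, adjusted p under 0.05), and 1469 had an unadjusted p under 0.05. The count was 0 without any 1 of the 3 controls, without the second or the third exposed library, without the receptor-positive libraries and with FPKM summed per locus. Lists called higher were antioxidant and detoxification enzymes (240 of 375 transcripts, relative median 0.17, adjusted p = 0.00328) and apoptosis and lysosome (195 of 335, median 0.08, adjusted p = 0.0291). Cuticle (120 of 167 lower, median -0.33, adjusted p = 0.0107), collagen (45 of 59, -0.24, adjusted p = 0.0107) and DNA replication (72 of 100, -0.14, adjusted p = 0.0286) were lower. None of the 5 held with an estimated correlation, with adjusted p = 0.825 to 0.915. Without the receptor-positive libraries, a control and an exposed one, 2 of them were called in the same direction.

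At 14 ppt the hepatopancreas had higher levels of ion pumps and mitochondrial transcripts as groups. Of 33 transcripts for Na+/K+-ATPase and V-type H+-ATPase 29 were higher and 4 lower (median log2 change 0.45, adjusted p = 1.1e-06), and of 190 for oxidative phosphorylation 138 were higher (0.28, adjusted p = 0.000445). With an estimated correlation these had adjusted p = 0.825 and 0.83. V-type proton ATPase subunit A (MSTRG.30241.1) was at 242 ± 40.8 FPKM at 0 ppt and 333 ± 69.1 FPKM at 14 ppt. The Na-K-Cl cotransporter (MSTRG.36703.1) was at 61.5 ± 29.8 and 191 ± 74.8 FPKM (log2 change 1.67, SE 0.48, adjusted p = 0.579). Betaine-homocysteine S-methyltransferase 1 (MSTRG.30485.1) was at 114 ± 63.2 FPKM. Over the osmolyte list alone 3 of 200 members fell, this transcript among them, and 1 rose, against 0 over all. The riser was nutrient amino acid transporter 1-like (MSTRG.37669.1), from 0.321 to 5.15 FPKM.

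Of 34966 transcripts 1 rose and 0 fell in hepatopancreas at 14 ppt (limma, adjusted p under 0.05), and 2421 had an unadjusted p under 0.05. The unnamed transcript MSTRG.35100.1, chosen after its values were seen, was listed at 0 at 0, 7 and 21 ppt and at 9.60 ± 4.603 FPKM at 14 ppt (adjusted p = 0.0137). The count was 0 without control 1 or 3 or the second or the third exposed library, and 5 without control 2. Without the receptor-positive libraries, the third control among them, 1 transcript passed, but another one. Further lists called higher were apoptosis and lysosome (234 of 335, median 0.24, adjusted p = 9.1e-05) and ribosomal proteins (153 of 205, 0.21, adjusted p = 7.7e-05). So were innate immunity (192 of 314, 0.14, adjusted p = 0.0107) and vitellogenesis and gonad (42 of 61, 0.36, adjusted p = 1.4e-05). Of the last list 4 members rose over the list alone and 0 over all. They were peritrophins, chitin-binding proteins of the gut lining and of egg coats, such as MSTRG.12337.1 with 120 FPKM at 0 ppt and 461 FPKM at 14 ppt. Hemocyanin (65 of 83 lower, -0.47, adjusted p = 0.00328) and other ion transporters (50 of 85, -0.15, adjusted p = 0.0456) were lower. None of these 6 held with an estimated correlation, with adjusted p = 0.719 to 0.915, and ribosomal proteins were no longer called after quantile normalization (adjusted p = 0.426). Without the receptor-positive libraries 6 of the 8 lists at 14 ppt were called in the same direction, and innate immunity (adjusted p = 0.0526) and other ion transporters (0.106) were not.

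At 21 ppt betaine-homocysteine S-methyltransferase 1 (MSTRG.30485.1) had the largest named fall in hepatopancreas. It went from 748 ± 317 to 21.4 ± 9.91 FPKM (SD, n = 3; log2 change -5.07, SE 0.51, adjusted p = 0.0175), with control libraries at 599, 533 and 1112 FPKM and exposed ones at 17.2, 32.8 and 14.3 FPKM. Over the list of osmolyte metabolism alone 5 of 200 members fell and 3 rose, against 1 fall over all. Those that fell included dimethylglycine dehydrogenase (MSTRG.30486.1, log2 change -3.80), whose locus sum (MSTRG.30486) passed over all loci with 47.5 ± 24.5 against 2.24 ± 0.438 FPKM (adjusted p = 0.0370). Another was glycine N-methyltransferase-like (MSTRG.12141.5), from 55.7 ± 23.6 to 7.203 ± 1.33 FPKM (log2 change -2.73, list-alone adjusted p = 0.00995). The 3 that rose were isoforms of nutrient amino acid transporter 1-like, the first of which (MSTRG.37669.1) went from 0.321 to 6.72 ± 4.82 FPKM.

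The sodium pump of the hepatopancreas was not past the threshold at 21 ppt. ATPase subunit beta-like (MSTRG.20654.2) was at 77.3 ± 22.1 FPKM at 0 ppt and 135 ± 30.1 FPKM at 21 ppt (log2 change 0.80, SE 0.26, adjusted p = 0.505), with all 3 exposed libraries above all 3 controls. The alpha subunit (MSTRG.6597.3) was at 55.8 ± 19.6 and 84.9 ± 23.3 FPKM (adjusted p = 0.589), and the Na-K-Cl cotransporter (MSTRG.36703.1) at 61.5 ± 29.8 and 104 ± 50.7 FPKM. V-type proton ATPase subunit A (MSTRG.30241.1) was at 242 ± 40.8 and 276 FPKM, carbonic anhydrase (MSTRG.34818.49) at 9.39 and 5.63 FPKM, and sodium/hydrogen exchanger 8-like (MSTRG.5804.2) at 4.67 and 5.496 FPKM. Glutamate dehydrogenase (MSTRG.11499.6) was at 69.9 and 81.4 FPKM and glutamine synthetase (MSTRG.23143.1) at 324 ± 74.6 and 213 ± 167 FPKM. Arginine kinase 3 (MSTRG.38078.1) was at 865 ± 159 and 951 ± 187 FPKM, and hemocyanin (MSTRG.15218.28) at 5415 ± 2466 and 3439 ± 1986 FPKM, none past the threshold.

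**Figure D3:**
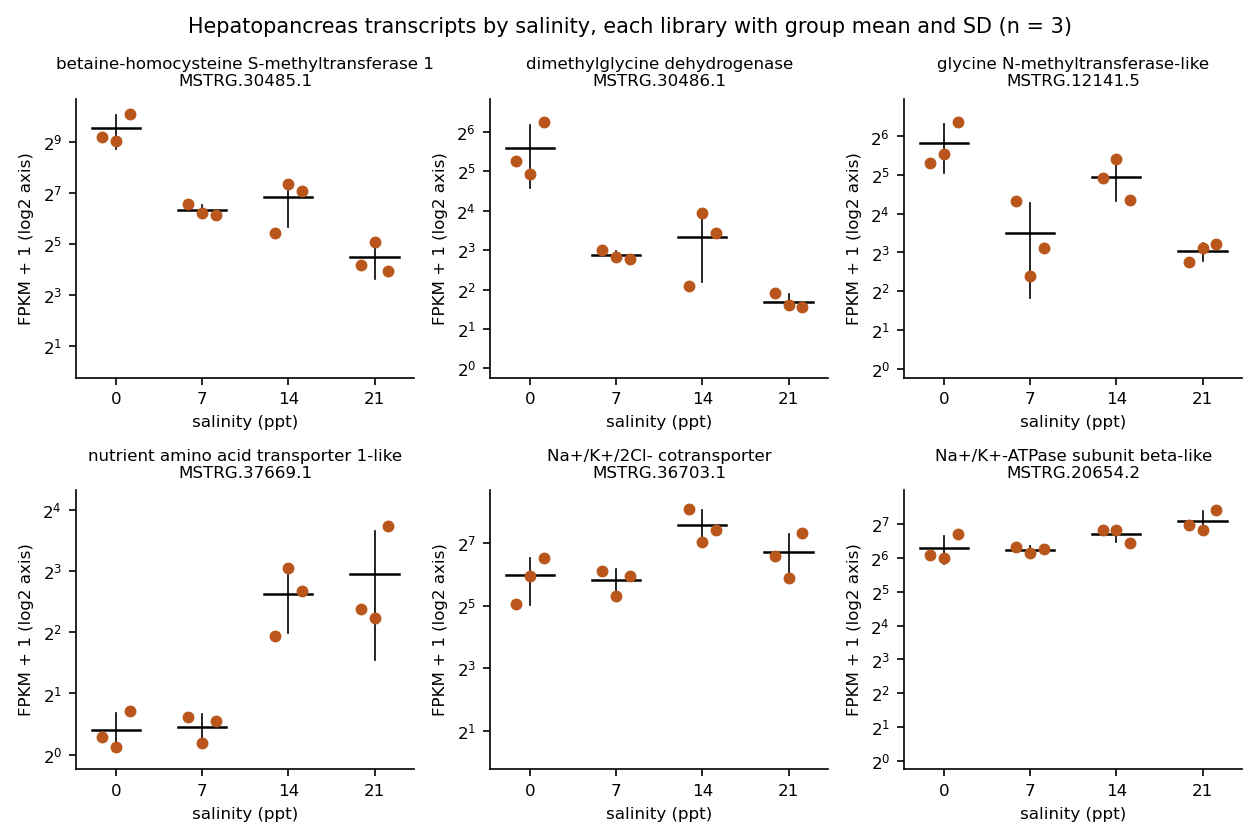
FPKM + 1 on a log2 axis against salinity (ppt) for 6 hepatopancreas transcripts; points are libraries, the line is the mean of 3 and the bar their SD. Betaine-homocysteine S-methyltransferase 1 goes from a mean of 748 FPKM at 0 ppt to 21.4 FPKM at 21 ppt.

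Of 34966 transcripts 2 rose and 1 fell in hepatopancreas at 21 ppt (limma, adjusted p under 0.05), and 3142 had an unadjusted p under 0.05. The risers, MSTRG.10567.3 and MSTRG.6980.1, are unnamed and were chosen after their values were seen. The count was 0 without control 2, 1 without control 1 or the first exposed library, 9 without control 3 and 23 without the third exposed library. The methyltransferase did not pass without control 1 (log2 change -5.19), control 2 (-5.27) or the first exposed library (-4.96). All 3 libraries of 21 ppt were receptor-positive, so no fit without them exists; with the receptor's level as a covariate the methyltransferase stood at -5.35 and did not pass.

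Lists higher in hepatopancreas at 21 ppt were oxidative phosphorylation (149 of 190, median 0.45, adjusted p = 3.7e-05), the ATPase pumps (30 of 33, 0.35, adjusted p = 0.00253) and heat shock proteins (165 of 243, 0.23, adjusted p = 0.034). DNA replication was higher as well (78 of 100, 0.20, adjusted p = 0.0210), but had adjusted p = 0.86 with the receptor's level as a covariate. Lower were contractile proteins (167 of 266, -0.26, adjusted p = 3e-06), cuticle (112 of 167, -0.33, adjusted p = 3.7e-05) and digestive enzymes (202 of 337, -0.18, adjusted p = 0.00109). Likewise lower were collagen (36 of 59, -0.23, adjusted p = 0.00252) and other ion transporters (53 of 85, -0.20, adjusted p = 0.00582). None of the 9 held with an estimated correlation, with adjusted p = 0.714 to 0.915. Over the list alone, chitinase MSTRG.31020.9, an enzyme that cleaves chitin, fell from 37.5 ± 23.1 to 0.400 ± 0.555 FPKM and a pair of isoforms of skeletal muscle actin 3 fell, against 0 over all in both lists.

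At 7 ppt transcripts of hemocyanin and of the cuticle were lower in muscle as groups. Of 39 hemocyanin and respiratory transcripts 33 were lower and 6 higher (relative median log2 change -0.91, adjusted p = 1.3e-21), and of 118 for cuticle, chitin and moulting 97 were lower (-0.93, adjusted p = 8.9e-18). With an estimated correlation both had adjusted p = 0.714. Over the list alone 13 hemocyanin transcripts, of the loci MSTRG.15218, MSTRG.15219 and MSTRG.36087, fell, against 0 over all. The most abundant (MSTRG.15218.28) was at 41.4 ± 3.77 FPKM (SD, n = 3) at 0 ppt and 10.03 ± 1.69 FPKM at 7 ppt (log2 change -1.95, SE 0.49, adjusted p = 0.622 over all). Hemocyanin is known to be made in the hepatopancreas, where it was at 5415 ± 2466 FPKM at 0 ppt.

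Of 22860 transcripts 0 rose and 1 fell in muscle at 7 ppt (limma, adjusted p under 0.05), and 807 had an unadjusted p under 0.05. The unnamed MSTRG.23187.1, chosen after its values were seen, was at 4.14 ± 0.183 FPKM at 0 ppt and at 0 at 7 ppt (adjusted p = 0.0390). The count was 0 without any 1 of the controls or the second or the third exposed library and 3 without the first, and 3 loci rose and 1 fell of 13377 with FPKM summed per locus. Digestive enzymes (60 of 103 lower, -0.18, adjusted p = 1.4e-05), oxidative phosphorylation (112 of 189, -0.25, adjusted p = 0.000242), ribosomal proteins (114 of 194, -0.15, adjusted p = 0.0301) and citrate cycle (41 of 65, -0.20, adjusted p = 0.0369) were also called lower. None of these 4 held with an estimated correlation, with adjusted p = 0.825 to 0.918.

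At 14 ppt 61 muscle transcripts rose together, and the same transcripts were abundant in gills at 14 ppt. Their median level per muscle library was 0, 0 and 0.0158 FPKM in the controls, 1.56, 1.40 and 1.36 FPKM at 7 ppt, 4.73, 4.24 and 7.18 FPKM at 14 ppt, and 2.29, 0.792 and 0.847 FPKM at 21 ppt. Their level in muscle at 14 ppt was 1.05% of that in gills at 14 ppt (median, quartiles 0.936% to 1.17%, range 0.510% to 3.22%), where the pair of receptor-positive libraries raised the mean. An informative protein name was given for 6 of the 61, elongation factor 1-alpha 1 (MSTRG.27321.1), which brings tRNA to the ribosome, and annexin-B9 (MSTRG.33674.2) among them. Elongation factor 1-alpha 1 went from 0.0692 to 5.05 FPKM (log2 change 2.46), and annexin-B9 was listed at 0 at 0 ppt and at 2.95 FPKM at 14 ppt. Both were chosen after their values were seen, since they lie under the mean of 5 FPKM that the rule asks for.

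Of 22860 transcripts 61 rose and 2 fell in muscle at 14 ppt (limma, adjusted p under 0.05), and 1055 had an unadjusted p under 0.05. The count was 24, 18 and 11 without control 1, 2 and 3, and 35 without the third exposed library; quantile normalization left 12.

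**Figure D4:**
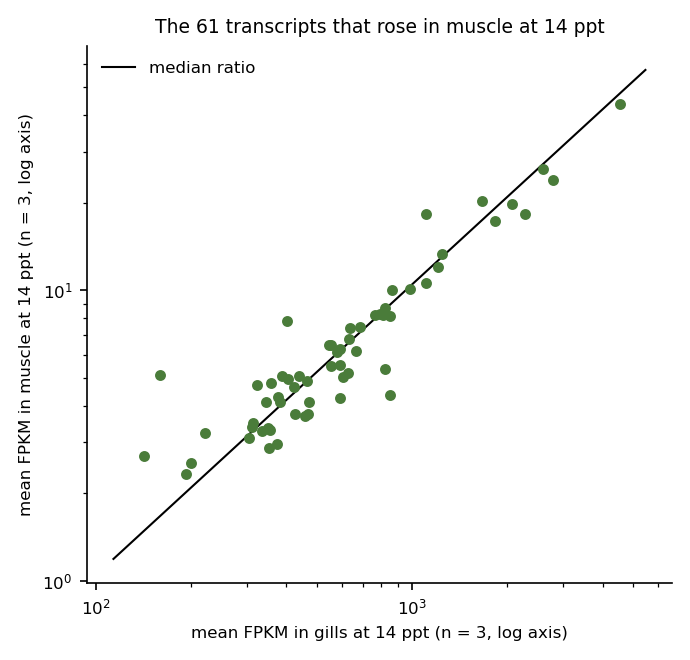
Mean FPKM in muscle against mean FPKM in gills, both at 14 ppt (n = 3 each, log axes), for the 61 transcripts that rose in muscle at 14 ppt; each point is 1 transcript. The line marks the median ratio of 1.05%.

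Lists called at 14 ppt in muscle were 12. Higher were heat shock proteins (173 of 204, relative median 0.26, adjusted p = 0.00485), translation factors (106 of 129, 0.16, adjusted p = 0.00507) and hemocyanin (30 of 39, 0.31, adjusted p = 0.003). The other 2 were DNA replication (44 of 53, 0.19, adjusted p = 0.0438) and proteasome (417 of 516, 0.15, adjusted p = 0.0439). Lower were cuticle (74 of 118, -0.69, adjusted p = 8.4e-12), contractile proteins (357 of 672, -0.24, adjusted p = 1.4e-05), and glycolysis and gluconeogenesis, the pathway that fuels fast contraction (36 of 57, -0.53, adjusted p = 0.000745). So were other ion transporters (64 of 129, -0.20, adjusted p = 0.0031) and collagen (56 of 121, -0.18, adjusted p = 0.011). The last were nervous system (52 of 102, -0.22, adjusted p = 0.0122) and oxidative phosphorylation (87 of 189, -0.11, adjusted p = 0.0344). None held with an estimated correlation, with adjusted p = 0.714 to 0.982. The second muscle library of 14 ppt stood apart, with 22785 transcripts at 1 FPKM or more against 15245 and 15384 in the others. Values of these lists without it are not given here. Elongation factor 1-alpha 1 among 129 translation factors and annexin-B9 in the list of cytoskeleton and junctions rose over all and over the list alone.

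At 21 ppt 4 loci of C-type lectins, sugar-binding proteins of innate immunity, rose in muscle when isoforms were summed per locus, though in none of the 4 with the replicate block. The lectin locus MSTRG.36202 went from 9.30 ± 1.59 to 134 ± 97.4 FPKM (SD, n = 3; log2 change 3.37, adjusted p = 0.0468), with exposed libraries at 232, 37.6 and 131 FPKM. The locus MSTRG.5023 went from 1.44 to 35.9 ± 26.5 FPKM (log2 change 3.53, adjusted p = 0.0468), and both were chosen after their values were seen. With the block their adjusted p was 0.107 and 0.0826. The same loci were far more abundant in hepatopancreas, where MSTRG.36202 was at 3957 FPKM at 0 ppt and 12118 FPKM at 21 ppt and MSTRG.5023 at 745 and 2873 FPKM. Material of hepatopancreas in the muscle samples was not tested as a source for them; 26 digestive enzyme transcripts were in muscle at 0.318% of their hepatopancreas level at 0 ppt and 0.603% at 21 ppt. Per transcript, 17 of 234 innate immunity members rose over the list alone and 0 over all, 16 of them lectins. With the block 18 rose, 15 of the 17 among them. The list as a whole was higher (186 of 234, relative median 0.28, adjusted p = 6e-06; adjusted p = 0.825 with an estimated correlation).

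A putative reverse transcriptase (MSTRG.18395.1), an enzyme of mobile elements, was the transcript named by the rule in muscle at 21 ppt. It rose from 0.0140 ± 0.0242 to 32.9 ± 13.5 FPKM (n = 3; log2 change 4.97, SE 0.51, adjusted p = 0.0123). With the replicate block it passed as well. The ion transport and metabolic genes followed in all tissues did not pass in muscle. Sodium pump alpha (MSTRG.6597.3) was at 80.1 ± 13.8 FPKM at 0 ppt and 84.4 ± 36.6 FPKM at 21 ppt, beta-like (MSTRG.20654.2) at 80.5 and 78.0 FPKM. The Na-K-Cl cotransporter (MSTRG.36703.1) was at 2.81 and 6.95 FPKM, V-type proton ATPase subunit A (MSTRG.30241.1) at 4.86 and 8.03 FPKM. Sodium/hydrogen exchanger 8-like (MSTRG.5804.2) was at 3.51 and 6.504 FPKM and carbonic anhydrase (MSTRG.34818.38) at 2.70 and 3.02 FPKM. Glutamate dehydrogenase (MSTRG.11499.4) was at 25.95 and 24.8 FPKM and glutamine synthetase (MSTRG.23143.1) at 56.4 and 28.9 FPKM. Arginine kinase 1 (MSTRG.38076.2), which buffers ATP in muscle, was at 8781 ± 959 and 9337 ± 1421 FPKM, and hemocyanin (MSTRG.15218.28) at 41.4 ± 3.77 and 16.8 ± 10.6 FPKM.

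Of 22860 transcripts 3 rose and 1 fell in muscle at 21 ppt (limma, adjusted p under 0.05), and 1120 had an unadjusted p under 0.05; with FPKM summed per locus 18 rose and 3 fell of 13377, or 3 and 2 with the replicate block as well. The count per transcript was 0 without control 1, 2 or 3 or the first exposed library, in which fits the reverse transcriptase stood at 4.76 to 4.99, 18 without the second exposed library and 1 without the third. With the replicate block the reverse transcriptase alone passed, and with only the 6 libraries compared and the block 0 did. Chosen after their values were seen, the other risers were the uncharacterized MSTRG.14653.1, from 0.502 to 11.4 ± 4.53 FPKM (log2 change 3.02, adjusted p = 0.0440), which reached 7445 FPKM in receptor-positive gill libraries, and the unnamed MSTRG.38457.1, while MSTRG.23187.1 fell.

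Further lists higher in muscle at 21 ppt were translation factors (111 of 129, relative median 0.21, adjusted p = 0.000164), hemocyte markers (41 of 48, 0.34, adjusted p = 0.00469) and ribosomal proteins (163 of 194, 0.14, adjusted p = 0.00483). The same held for apoptosis and lysosome (116 of 158, 0.14, adjusted p = 0.00722) and the ATPase pumps (28 of 30, 0.24, adjusted p = 0.0104). Lower were cuticle (78 of 118, -0.58, adjusted p = 6.2e-13), hemocyanin (26 of 39, -0.63, adjusted p = 6.5e-09), contractile proteins (349 of 672, -0.24, adjusted p = 0.000318) and collagen (57 of 121, -0.11, adjusted p = 0.0107). None of these 9 held with an estimated correlation, with adjusted p = 0.714 to 0.915.

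Tissues were compared in their response to 21 ppt. Sodium-potassium ATPase beta (MSTRG.20654.1) responded by -2.85 in gills and 0.62 in hepatopancreas (difference -3.46, SE 0.58, adjusted p = 0.0488). The sum of its locus did not pass (-1.46, adjusted p = 0.218), nor did the transcript with the replicate block (adjusted p = 0.202). The difference was called for betaine-homocysteine S-methyltransferase 1 (MSTRG.30485.1) too, with -0.01 and -5.07 (difference 5.06, SE 0.76, adjusted p = 0.0193). Timeless (MSTRG.6449.1), a gene of the circadian clock and of replication forks, responded by -1.33 in gills and 1.74 in hepatopancreas (difference -3.07, SE 0.52, adjusted p = 0.0488), but not as the sum of its locus (-1.96, adjusted p = 0.0649) or with the block (adjusted p = 0.0519). The reverse transcriptase (MSTRG.18395.1) responded by -1.10 in gills and 4.97 in muscle (difference -6.06, SE 0.88, adjusted p = 0.0128). As a list, the ATPase pumps responded lower in gills than in hepatopancreas (median difference -0.65, adjusted p = 4.8e-07) and muscle (-0.75, adjusted p = 0.0029). This test, at the preset correlation, was added after the data were seen and was not run with an estimated one. Unlike the calls, its medians are not relative to all transcripts and include any general shift.

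Between gills and hepatopancreas 1 response was higher and 3 were lower in gills of 26747 transcripts (limma, adjusted p under 0.05), with 1096 at an unadjusted p under 0.05. The count was 0 to 12 when 1 of the 12 libraries was left out, with a move in 9 of 12 fits, and 1 with the receptor's level as a covariate. Between gills and muscle the counts were 0 and 1 of 20265 (820 at an unadjusted p under 0.05), with 0 to 2 calls when 1 library was left out and 0 with the covariate, and between hepatopancreas and muscle 0 of 16200 (629), with 0 to 11 when 1 library was left out. In the same list test DNA replication responded higher in gills than in hepatopancreas (0.60, adjusted p = 3.3e-06) and muscle (0.50, adjusted p = 6.9e-05). Hemocyanin (-0.98, adjusted p = 1.4e-05), oxidative phosphorylation (-0.33, adjusted p = 6.8e-06) and citrate cycle (-0.26, adjusted p = 0.000273) responded lower in gills than in hepatopancreas. Contractile proteins responded lower in hepatopancreas than in muscle (-0.80, adjusted p = 5.5e-09), as did digestive enzymes (-0.51, adjusted p = 0.000501), while hemocyanin (0.33, adjusted p = 0.00188) and oxidative phosphorylation (0.10, adjusted p = 0.00188) responded higher. Lower in gills than in muscle were contractile proteins (-0.48, adjusted p = 0.0018) and digestive enzymes (-0.49, adjusted p = 0.00138). So were innate immunity (-0.40), ribosomal proteins (-0.39) and translation factors (-0.36), with adjusted p = 0.0283 each.

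**Figure D5:**
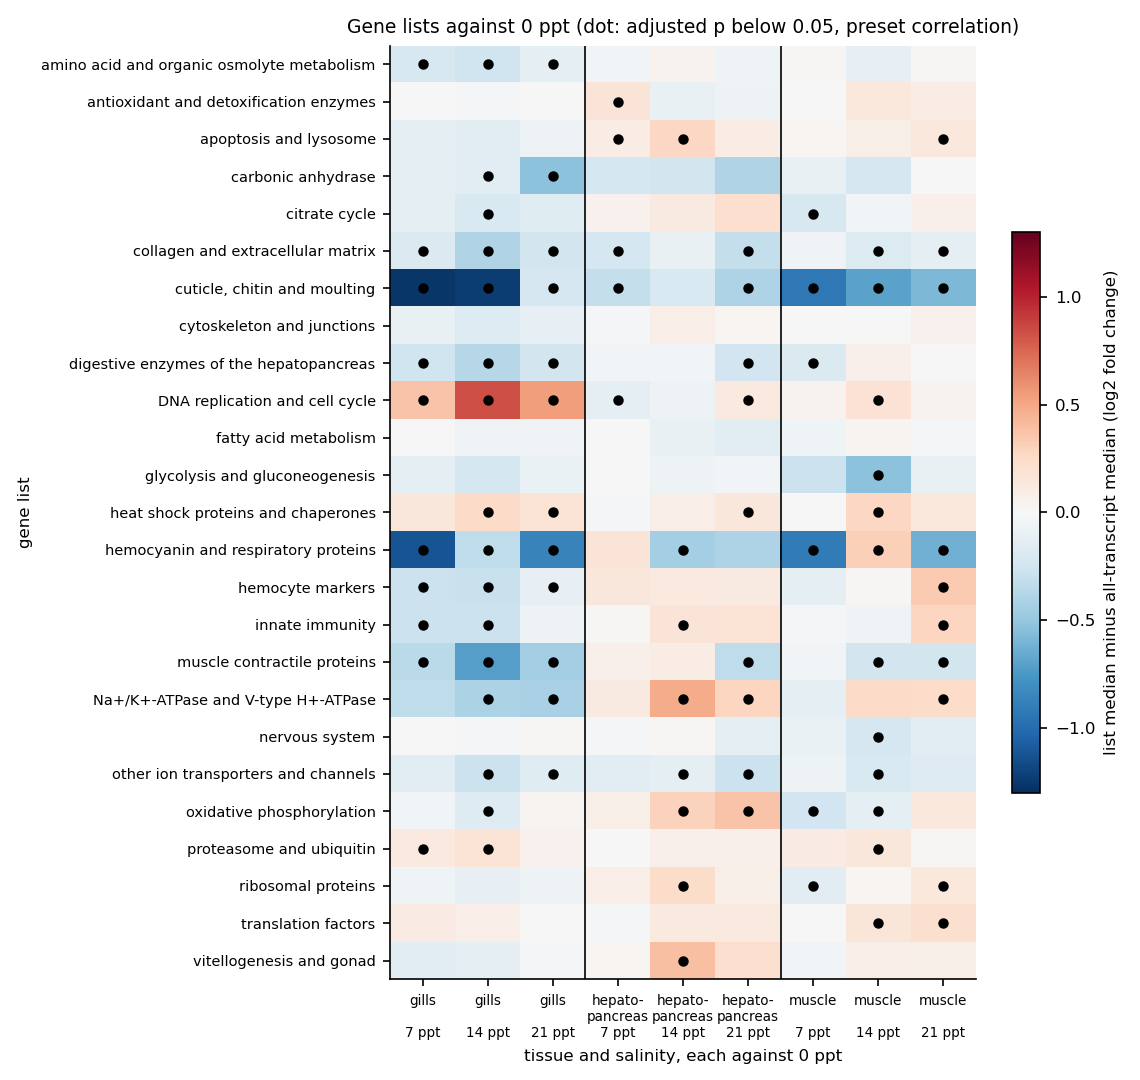
Median log2 change of each gene list minus that of all transcripts tested, for 7, 14 and 21 ppt against 0 ppt (n = 3 each) in the 3 tissues; a dot marks an adjusted p under 0.05 at the preset correlation. Cuticle, chitin and moulting is called lower in 8 of 9 columns, and no call held with an estimated correlation.

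Over the 9 comparisons 88 of 225 list tests passed at the preset correlation, 30 higher and 58 lower, and 0 with the correlation estimated from the data, where the smallest adjusted p was 0.714. Drawn orders of the salinity labels gave 34 to 100 calls, with a median of 62. Cytoskeleton and junctions (smallest adjusted p = 0.104) and fatty acid metabolism (0.139) were called in none of the 9. Glycolysis and nervous system were called in muscle at 14 ppt alone, antioxidant enzymes in hepatopancreas at 7 ppt alone, and vitellogenesis and gonad in hepatopancreas at 14 ppt alone. In 9 calls the median or the mean of the members had the other sign than the test, and in 0 relative to the median of all transcripts. These were carbonic anhydrase and osmolyte metabolism in gills at 14 ppt, osmolyte metabolism in gills at 21 ppt, other ion transporters, oxidative phosphorylation, nervous system and collagen in muscle at 14 ppt, and contractile proteins and collagen in muscle at 21 ppt. After quantile normalization 73 of the 88 calls kept their direction and call, and 64 with FPKM summed per locus.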

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

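The tests of the ovary-type transcripts against ovary RNA and salinity, and all tests of the muscle rises and of the all-or-none transcripts, were chosen after the results were seen.

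Responses to 21 ppt that differed between tissues in the test of the difference itself were 5. Sodium-potassium ATPase beta (MSTRG.20654.1) differed by -3.46 on the log2 scale between gills and hepatopancreas (adjusted p = 0.0488), but not as the sum of its locus (-1.46, adjusted p = 0.218). Betaine-homocysteine S-methyltransferase 1 (MSTRG.30485.1) differed by 5.06 between gills and hepatopancreas (adjusted p = 0.0193). Timeless (MSTRG.6449.1) differed by -3.07 between gills and hepatopancreas (adjusted p = 0.0488), with the locus sum at -1.96 (adjusted p = 0.0649). An unnamed transcript (MSTRG.12973.1) differed by -7.65, with -3.50 in gills and 4.15 in hepatopancreas (SE 0.99, adjusted p = 0.00383). The putative reverse transcriptase (MSTRG.18395.1) differed by -6.06 between gills and muscle (adjusted p = 0.0128).

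Ovary-type transcripts stood high in 5 exposed gill libraries, with the vitellogenin receptor (MSTRG.26814.1) at 65.6 to 190 FPKM and the uncharacterized MSTRG.14653.1 at up to 7445 FPKM. Of 37 ovary and germline markers listed before the test, 14 of which control gills also had at 1 FPKM or more, at least 80% stood above all controls in 2 exposed libraries, where ovary RNA in the sample was to give at least 3; the shares in the receptor-positive libraries were 78.4% at 7 ppt, 83.8% and 83.8% at 14 ppt and 78.4% and 78.4% at 21 ppt, beside 62.2% and 29.7% in the others of 7 ppt, 73.0% in the other of 14 ppt and 16.2% in the other of 21 ppt, so RNA of ovary in the sample may be the source but is not settled. A wrong tissue label is argued against, since 386 gill transcripts kept a median of at least 40.6% of their control level in every exposed gill library. Their highest median there was 77.0%, so they were lower than in controls in each of these libraries. Salinity as the cause remains open, since 5 of 9 exposed libraries against 0 of 3 controls gave an exact Fisher p of 0.205. Maturity of the animals, which the labels do not give, was not tested.

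The 61 rises in muscle at 14 ppt may be RNA or reads from ovary-rich material, since 96.7% of them lay within a factor of 2 of a single muscle to gill ratio of 1.05%, against 42.5% of 22774 other transcripts around their own median of 53.3%; 1.17% of those lay within a factor of 2 of the median of the rises. Tissue taken along in dissection and reads carried over between libraries would both give a single ratio. The median level of the rises was also similar within muscle at 14 ppt, at 4.73, 4.24 and 7.18 FPKM. It was 4.52 FPKM in the receptor-negative gill library of 14 ppt and 5.45, 2.14 and 2.57 FPKM in hepatopancreas. Control gills were uneven, at 0, 4.41 and 0.0760 FPKM. Dissection would have to bring similar amounts into each library of 14 ppt, which was not tested. A general rise of material from other tissues at 14 ppt is not settled: 26 digestive enzyme transcripts were in muscle at 0.318% of their hepatopancreas level at 0 ppt, 0.179% at 7 ppt and 0.555% at 14 ppt, a ratio of 1.75 to 0 ppt, and at 0.603% at 21 ppt. The ratio of the rises themselves was 0.374%, 1.05% and 0.299% of gills at 7, 14 and 21 ppt. At 0 ppt it was 1.17%, with median levels of 0.0239 FPKM in muscle and 1.84 FPKM in gills. That ratio rests on muscle values near 0 and mainly on 1 of the 3 gill controls. No biological explanation was tested.

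Some transcripts were present in some libraries of a group and absent from others in both of 2 tissues, and equal replicate numbers in different tissues may stand for the same animals. Taking 5 FPKM as present and 1 FPKM as absent, states matched between equal numbers in 735 of 1116 cases in gills and hepatopancreas (93 transcripts, median of all 1296 orders 599), 78 of 132 in gills and muscle (median 72) and 100 of 132 in hepatopancreas and muscle (11 transcripts, median 80). One-sided exact permutation p-values were 0.0617, 0.183 and 0.00849, or 0.0926, 0.183 and 0.0255 after adjustment over the 3 pairs. The thresholds were set after the data were seen and other pairs were tried: with 0.5 FPKM as absent and 5 or 20 FPKM as present, the adjusted exact p for hepatopancreas and muscle was 0.130 (5 transcripts, 44 of 60 states) and 0.111 (1 transcript, 12 of 12). The rule that all 3 threshold pairs must pass was set after the first result was seen. The question stays open. Replicate numbers were used across tissues in 1 check alone, of the difference between tissues taken per salinity and replicate number, and its count did not move.

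Counts of changed transcripts were compared with other splits of the same libraries. The 10 splits of 3 against 3 are too few for a share under 0.05. In gills 1 split gave as many as the real 18 at 7 ppt (highest other 4), 1 as many as the real 6 at 14 ppt (highest other 3) and 2 as many as the real 22 at 21 ppt, where another split called 54, which points to a structure of the samples other than salinity. In hepatopancreas 7, 6 and 5 splits gave as many as the real 1, 1 and 3 (highest other 14, 10 and 15), and in muscle 6, 1 and 1 as many as the real 1, 63 and 4 (highest other 2, 3 and 3). At 21 ppt, where equal numbers deviated together, the 4 splits that part all 3 pairs gave the real 22 against at most 0 in gills and the real 4 against at most 2 in muscle. The 54 came from a split that leaves pairs together, so structure shared within pairs is a possible source of it. For the linear trend, the share was under 0.05 for the real 1 in gills (4 of 100 drawn orders, highest other 1), in the fit without the replicate block alone. The orders ignore the pairs, and with the block 0 passed. Chance cannot be excluded for the real 0 in hepatopancreas and in muscle (100 of 100 each, highest other 1 and 2). For the difference between tissues the share was under 0.05 for the real 4 of gills and hepatopancreas (4 of 100, highest other 6). That was again in the fit without the block, which left 2. It was not for the real 1 of gills and muscle (29 of 100, highest other 4) or the real 0 of hepatopancreas and muscle (100 of 100, highest other 5). For the number of gene lists called, 2 of 100 drawn orders gave as many as the real 88, with 100 in the other one and a median of 62 over the other orders. These shares are not adjusted over the counts tested. The orders of the list test also ignore the pairs and the receptor-positive libraries, and 0 calls held with an estimated correlation. Chance is therefore not excluded for any of these counts.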

How the results depend on the processing

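FPKM summed per locus, the fits without the vitellogenin receptor libraries the fits with the receptor as a covariate and those of only the 6 libraries compared or of locus sums with the replicate block were chosen after the data were seen. Counts of changed transcripts are small and moved with most settings; where fewer libraries were fitted or spread was estimated from fewer, calls can end for that reason alone, and otherwise the cause was not tested. Read depth is unknown, so what it limits cannot be said, and transcripts near 1 FPKM enter or leave with the pseudocount and the filter. Leaving out the receptor libraries could not be run for hepatopancreas at 21 ppt, where all 3 exposed libraries are among them, and muscle has none. Replicate numbers were taken as pairs for 0 and 21 ppt in gills and muscle alone, where the block changed no other call per transcript, list or list member than those given in the report and here. It was fitted to differences between tissues per transcript, and not to those per locus or to list tests per locus. After centring by salinity, the correlation between libraries of equal number and different salinity was over 0.1 in 10 of 18 cases in gills (-0.298 to 0.525), 1 of 18 in hepatopancreas (-0.176 to 0.118) and 7 of 18 in muscle (-0.323 to 0.242), and 8, 2 and 7 of 12 libraries correlated best with their own number. Where numbers do not pair, the block ended the calls of turripeptide (MSTRG.6710.1) in gills at 7 and 14 ppt, of the methyltransferase (MSTRG.30485.1) in hepatopancreas at 21 ppt, and of other ion transporters as a list in hepatopancreas at 14 ppt (adjusted p = 0.0564), without a change of direction, and citrate cycle was called in hepatopancreas at 21 ppt (adjusted p = 0.0477 against 0.0519). Over the list alone at 21 ppt, beside the changes given above, it gave 1 fall among the ATPase pumps of gills against 0. In muscle it gave 0 rises against 1 in apoptosis and lysosome and in vitellogenesis and gonad each. With a minimum log2 change of 1 none of the 9 counts changed.

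Gills at 7, 14 and 21 ppt had 18, 6 and 22 changed transcripts. A pseudocount of 0.1 gave 11 (5 rises) at 14 ppt and 7 (4 rises) at 21 ppt, no filter 26 at 14 ppt, and quantile normalization 25 at 14 ppt and 42 at 21 ppt. The replicate block gave 3, 3 and 3, locus sums 5, 1 and 5 (2 at 21 ppt with the block), the fit without receptor libraries 1, 1 and 0, the covariate 4, 3 and 3, and the fit of only the 6 libraries compared 11, 274 (190 rises) and 10 (5 rises), or 0 at 21 ppt with the block. Hepatopancreas had 1, 1 and 3. The pseudocount gave 0 at 7 ppt and 4 at 14 ppt, no filter 5, 6 and 50, quantile normalization 2 at 14 ppt and 5 at 21 ppt, the block 0, 0 and 0, locus sums 0 at 7 ppt and 6 at 21 ppt, no receptor libraries 0 at 7 ppt, the covariate 0, 0 and 1, and only the 6 libraries 0, 2 and 0. Muscle had 1, 63 and 4. The pseudocount gave 26 at 7 ppt and 33 at 21 ppt, no filter 11, 195 and 32, quantile normalization 12 at 14 ppt, the block 0 at 7 ppt and 1 at 21 ppt, locus sums 4 at 7 ppt and 21 at 21 ppt (5 with the block), and only the 6 libraries 0, 32 and 8, or 0 at 21 ppt with the block. Leaving out 1 library gave 0 to 4, 0 to 8 and 0 to 20 in gills, 0 to 1, 0 to 5 and 0 to 23 in hepatopancreas, and 0 to 3, 11 to 57 and 0 to 18 in muscle.

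The trend had 1 in gills, with 0 for no filter, the block, no receptor libraries and the covariate, 2 for locus sums and 10 by the F test; it had 0 in hepatopancreas, with 2 for the covariate and 5 by the F test, and 0 in muscle, with 29 by the F test. Leaving out 1 library gave 0 to 5, 0 to 0 and 0 to 1. Gills and hepatopancreas differed in 4, with 125 for no filter, 2 for quantile normalization, the block and locus sums each, and 1 for the covariate. Gills and muscle differed in 1, with 2 for the pseudocount, the block, locus sums and no receptor libraries each, 74 for no filter and 0 for the covariate. Hepatopancreas and muscle differed in 0, with 116 for no filter and 1 for the block and the covariate each. Leaving out 1 library gave 0 to 12, 0 to 2 and 0 to 11. Of 225 list tests 88 passed, with 0 for the estimated correlation, 57 for no filter and 77 to 101 when 1 library was left out. The direction of blastula protease 10-like (MSTRG.10624.7) in gills at 21 ppt reversed with locus sums (-0.0356), and the cause was not tested. Other calls of named genes that ended kept their direction; when 1 library was left out, 549 values of named genes stayed on their side of the threshold and 45 lost the call with the same direction.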

Other observations

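Transcripts typical of the male germline were also seen in some libraries, for part of them in controls too, without a test. In gills, dual specificity testis-specific protein kinase 2 (MSTRG.37018.1) had 337 FPKM in the first library of 14 ppt and at most 0.769 FPKM in the other 11, and sperm motility kinase Y-like (MSTRG.3395.1) had 77.7 FPKM in the same library and at most 0.115 FPKM in the others. Sperm gelatinase (MSTRG.24807.1), a protease of crustacean sperm, had 2363 FPKM in that library, 1037 FPKM in the first library of 7 ppt, 255 FPKM in control 1 and 45.5 FPKM in control 3. It had 217 FPKM in the second library of 14 ppt, 163 FPKM in the first of 21 ppt and 21.8 FPKM in the third of 21 ppt. Testis-specific gene A8 (MSTRG.37909.1) had 163 FPKM in the first gill library of 21 ppt 27.6 FPKM in the third of 21 ppt, and 62.5 and 39.2 FPKM in controls 3 and 1. The second library of 14 ppt and the third of 21 ppt also had the vitellogenin receptor (113 and 65.6 FPKM).

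In muscle at 21 ppt the locus of lectin 2 (MSTRG.5024) went from 1.03 to 25.8 ± 19.0 FPKM (log2 change 3.37, adjusted p = 0.0468), a further C-type lectin locus (MSTRG.28402) from 0.248 to 13.2 ± 9.75 FPKM (adjusted p = 0.0484), and a keratin-associated protein 16-1-like locus (MSTRG.23030) from 2.43 to 60.4 ± 49.3 FPKM (adjusted p = 0.0468). In hepatopancreas MSTRG.5024 was at 443 FPKM at 0 ppt and 2083 FPKM at 21 ppt, and MSTRG.28402 at 174 and 862 FPKM. With the replicate number as a block none of the 3 muscle loci passed (adjusted p = 0.0973, 0.107 and 0.107). These loci were chosen after their values were seen.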
